A study of Mus musculus with 6 samples.

How the data were processed

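Microglia from male C57BL/6J mice, aged 10 weeks, were compared at 3 and 10 days after injection of 2 µl of 1% lysolecithin (LPC) into the corpus callosum, with 3 libraries per time point. The labels describe flow sorting of live CD11b positive, Ly6G and CD3 negative, CD45 low cells, amplification of cDNA from polyadenylated RNA with a NuGEN Ovation kit, and paired reads of 100 bp. Per the submitters' processing notes, STAR 2.5.2a, R 3.3.2, edgeR 3.16.5, limma 3.30.8 and the GRCm38 genome were used. The counting program, the annotation release and the strand of the libraries are not given in the sources used here.

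The deposited count table holds raw counts per Ensembl gene (24984 genes, 5349 of them at 0 in all libraries). The authors' normalized table holds log2 values. Each column equals log2 of the count plus 0.5 minus 1 constant per library (largest deviation 0.0095). The deposited FPKM table holds 49671 genes and 1 line that is not a gene. Its 24687 genes outside the count table were at 0 throughout, and its columns are named by time point only, so its values were used by group. The authors also deposited a table of log2 fold changes with an unadjusted p-value per gene. Its sign was tested against the normalized table and is day 3 minus day 10 (r = −0.996 with day 10 minus day 3). Symbols came from the FPKM table (24969 identifiers), and positions, exon overlaps and exon lengths from GENCODE M21 (GRCm38, 24893 identifiers matched). Of identifiers sharing a symbol, 14 with the smaller total were not used under that symbol.

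Columns were matched to libraries by the sample number given in both the labels and the column names. Each library stands for 1 mouse. Library totals ran from 5890081 to 9212197 counts. These are counts assigned to genes, not reads sequenced, and amplified reads without molecular identifiers are not independent molecules. Detected genes were also compared after thinning each library in expectation to 5890081 counts.

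Group tests used edgeR 4.0.16 in R 4.3.3 (filterByExpr with a minimum count of 10, TMM normalization, quasi-likelihood F-test, model with group only). A gene was called at a Benjamini-Hochberg adjusted p under 0.05, over 10535 genes. Levels are TMM-scaled CPM, and log2 CPM used a prior count of 2. The SE given with an edgeR log2 fold change was derived from the test. It is the absolute log2 fold change divided by the square root of the F statistic. Each of 23 pathway lists was tested with camera (limma 3.58.1) with a preset correlation of 0.01, adjusted over the lists. The lists were homeostatic microglia, damage-associated microglia, type I interferon-stimulated, interferon receptor and nucleic acid sensing, MHC class I, MHC class II, necroptosis, apoptosis, inflammasome and pyroptosis, pro-inflammatory, alternative-activation, secreted factor, cell cycle, cholesterol synthesis, lipid uptake, storage and efflux, lysosomal, phagocytic, complement, glycolysis, oxidative phosphorylation, ribosomal protein, matrix, and immediate-early and heat-shock genes. The 14 lists of cell type markers were adjusted separately, and a list needed at least 3 tested members. Their summed CPM was compared by a two-sided exact permutation test in R 4.3.3. Thinning used Python 3.11.15 with scipy 1.17.1.

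The tests, lists, named genes and most alternatives were chosen before the data were examined. The genes named were the 8 called genes of largest rise and of largest fall with a mean CPM of at least 5 and no overlap between groups, leaving out symbols of the Gm and Rik types. With them came, for each pathway list, the 2 called members of smallest p in each direction, or the 2 members of smallest p where none was called. A fixed set of 23 genes of microglia, interferon, cell death, cytokine and cell cycle function, and the most abundant member of each marker list, completed the rule. Genes named outside it are said to be so or are marker list members, and some genes that the rule or the lists hold are not reported here.

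Alternatives were RLE, upper-quartile and library-size scaling, no low-count filter, a filter of 1 CPM in at least 3 libraries, DESeq2 1.42.0, limma-voom with and without sample quality weights, and the replicate number as a block. Further ones were limma-trend on log2 of FPKM plus 1 or plus 0.1, the same after leaving out genes with mean FPKM under 1, an adjusted p under 0.01, and an absolute log2 fold change of at least 1. Others were camera with an estimated correlation, the fry rotation test, and leaving out each library in turn. A robust edgeR fit, and 3 scalings of the fit without LPC day 10 replicate 3, were added after the data were seen.

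The procedure was tested on simulated data with 50 genes at each of 4 fold changes over the spread of these libraries. It called 0%, 2%, 14% and 26% of the genes at absolute log2 fold changes of 1, 2, 4 and 6, with 0 false calls among unchanged genes. A 4-fold lowering of the cell cycle list was called by camera with the preset correlation (adjusted p = 4.85e-06) and not with an estimated correlation (0.0938), with 0 other lists called. Genes were simulated independently of each other, and no library was made to stand apart. In the data the estimated correlation within the cell cycle list was 0.40. The simulation therefore cannot show how often false calls arise with correlated genes or an outlying library.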

Results

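Polyadenylated RNA was sequenced from microglia, the resident macrophages of the brain, sorted from demyelinated lesions of the mouse corpus callosum. The lesions were made by stereotaxic injection of lysolecithin (LPC), a lipid that strips myelin. The libraries fell into 2 groups, LPC day 3 and LPC day 10, with 3 libraries each and 1 mouse per library as the design text gives it. The count table held 9093567, 7005939 and 9212197 counts for LPC day 3 replicates 1, 2 and 3. It held 6633766, 9021700 and 5890081 counts for LPC day 10 replicates 1, 2 and 3. There were no uninjured or vehicle-injected libraries in the sample list, so each value below compares the late with the early lesion.

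LPC day 10 replicate 3 stood apart from the other 5 libraries. Thinned to the lowest total, 10416 genes had a count in it, against 12074.4 to 15814.4 in the others. Of the 10535 genes tested, 1622 (15.4%) had no count in it, against 58 to 566 in the others. In it 357 genes lay at least 8-fold above each of the other libraries, against 7 to 57 such genes in the others. Across genes, Pearson correlations of log2 CPM (counts scaled by library size) were 0.575 to 0.612 for the 5 pairs that included it and 0.621 to 0.699 for the other 10 pairs. The first principal component held 46.2% of the variance and placed it at 261.5, with the other libraries between −65.28 and −33.60. The share of counts in mitochondrial ribosomal RNA ran from 27.1% to 31.8% at day 3 and was 9.32%, 32.9% and 14.5% in LPC day 10 replicates 1, 2 and 3.

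**Figure D1:**
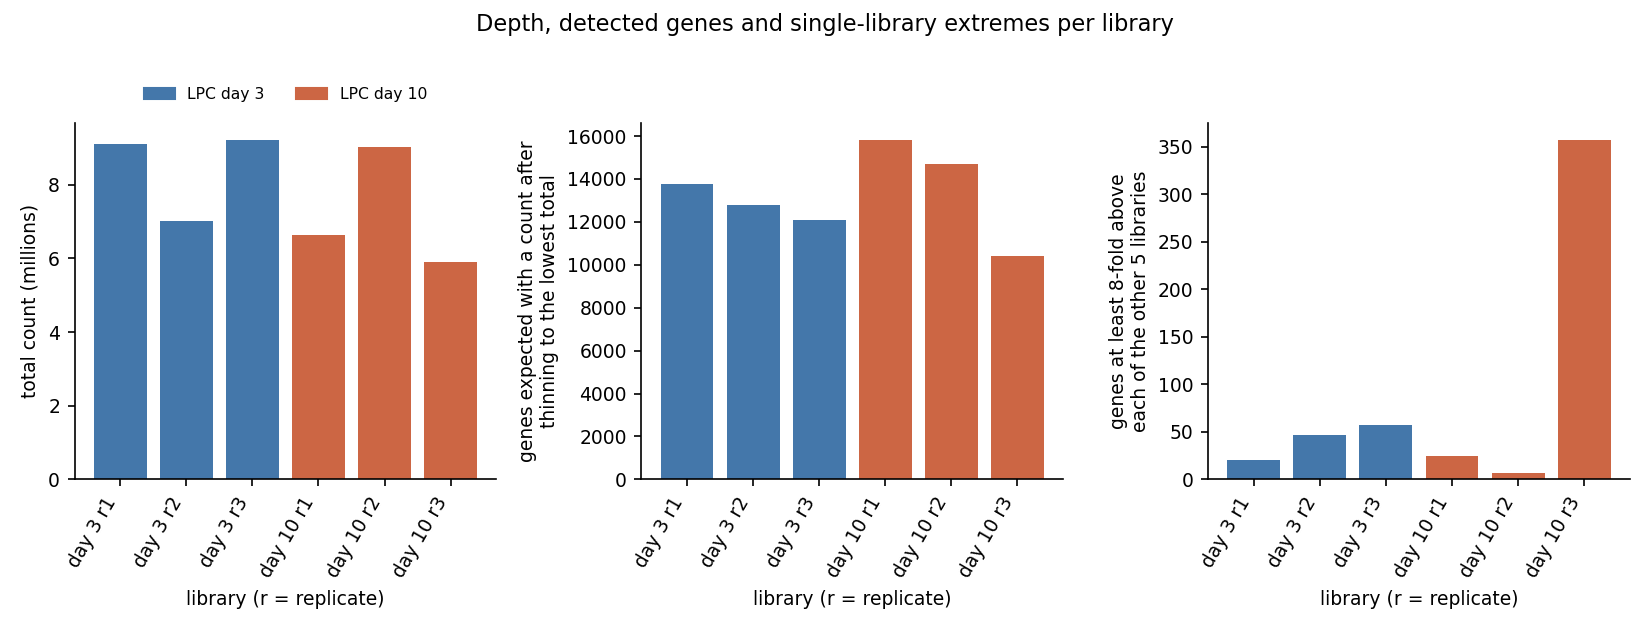
Total counts (left), genes expected with a count after thinning to the lowest total (middle) and genes at least 8-fold above each of the other 5 libraries (right), one bar per library, blue for LPC day 3 and orange for LPC day 10. LPC day 10 replicate 3 had the lowest total (5890081), the fewest detected genes (10416) and the most genes far above the rest (357).

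The design gives 1 comparison, day 10 against day 3, which asks how gene expression in microglia of a remyelinating lesion differs between the late and the early time point. With a preset correlation between genes, the list of type I interferon-stimulated genes was called higher at day 10 (35 of 41 tested members positive, median log2 fold change 1.26) and the list of cell cycle genes lower (30 of 34 negative, median −1.37). Both calls were lost with an estimated correlation (adjusted p = 0.984 for each) and with a rotation test (0.976), and the interferon call also when each of 4 libraries in turn was left out, with no low-count filter and with a replicate block. By single genes, 12 rose and 0 fell, and all 12 had their highest level in LPC day 10 replicate 3. Without that library, genes of the interferon response, of the damage-associated microglia state, of MHC class I presentation, of inflammation and of cholesterol synthesis were called higher as lists, and homeostatic microglia genes and cell cycle genes lower, with the preset correlation. With an estimated correlation 0 of these 7 lists were called (lowest adjusted p 0.239), and 0 with the rotation test for a shared direction (0.0814). The form of the rotation test that allows members to change either way gave adjusted p of 0.00854 for damage-associated and 0.0383 for cholesterol synthesis genes. For the rest of the 7 it gave at least 0.0809, and outside them 0.0032 for lipid uptake, storage and efflux genes.

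In edgeR's quasi-likelihood test at a Benjamini-Hochberg adjusted p under 0.05, 12 genes rose and 0 fell, with a lowest adjusted p of 0.0528 among genes with a negative change. At an unadjusted p under 0.05 there were 501 genes with a positive and 145 with a negative change, where 526.8 in all would be expected by chance. DESeq2 called 80 genes higher and 33 lower and shared 1 gene with edgeR. limma-voom called 0 and 1, limma-voom with sample quality weights 2 and 1, and limma-trend on FPKM 0 and 0. The number called higher depended on each library: it was 36, 41 and 26 without LPC day 3 replicates 1, 2 and 3, and 208, 169 and 1 without LPC day 10 replicates 1, 2 and 3. The biological coefficient of variation was 1.11.

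The called genes of largest rise were Zfp286, Pigh, Dvl1, Col10a1, Snx8, Spidr, Ibtk and Cstb. Snx8 (ENSMUSG00000029560, GRCm38 chromosome 5, 140340299 to 140389262), a sorting nexin of endosomes, rose by 6.24 ± 1.30 (log2 fold change ± SE, n = 3 libraries per group, edgeR adjusted p = 0.0388). Its level was 7.93 ± 6.91 CPM at day 3 (SD, n = 3) and 601.5 ± 1010 at day 10, of which LPC day 10 replicate 3 alone had 1767 CPM and replicates 1 and 2 had 19.7 and 17.7. Cstb (ENSMUSG00000005054, chromosome 10, 78425669 to 78427622), an inhibitor of cysteine cathepsins, rose by 5.16 ± 1.13 (edgeR adjusted p = 0.0450, n = 3). It had 51.5, 27.9 and 1307 CPM in LPC day 10 replicates 1, 2 and 3, and 12.9 ± 2.84 CPM at day 3. The log2 fold changes of the other named genes were 7.85 for Zfp286, 7.69 for Pigh, an enzyme subunit of GPI-anchor synthesis, 7.16 for Dvl1, a Wnt signalling protein, 6.57 for the collagen gene Col10a1, 6.15 for the DNA repair gene Spidr and 5.31 for Ibtk. Exons of Spidr overlap those of Cebpd, exons of Pigh those of Plekhh1, exons of Dvl1 those of Tas1r3 and exons of Col10a1 those of Nt5dc1, so reads there are not assigned to 1 gene by position alone. LPC day 10 replicate 3 held a median of 97.2% of the day 10 sum of the 12 called genes. Without it 0 of the 12 were called (edgeR, lowest adjusted p 0.776) and their median log2 fold change was 2.27, with a range of 0.70 to 3.69 against a median of 6.58 with all libraries. Cstb was also not called without LPC day 3 replicate 3 (edgeR adjusted p 0.0577), nor Dvl1 without LPC day 3 replicate 1 (0.0537).

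**Figure D2:**
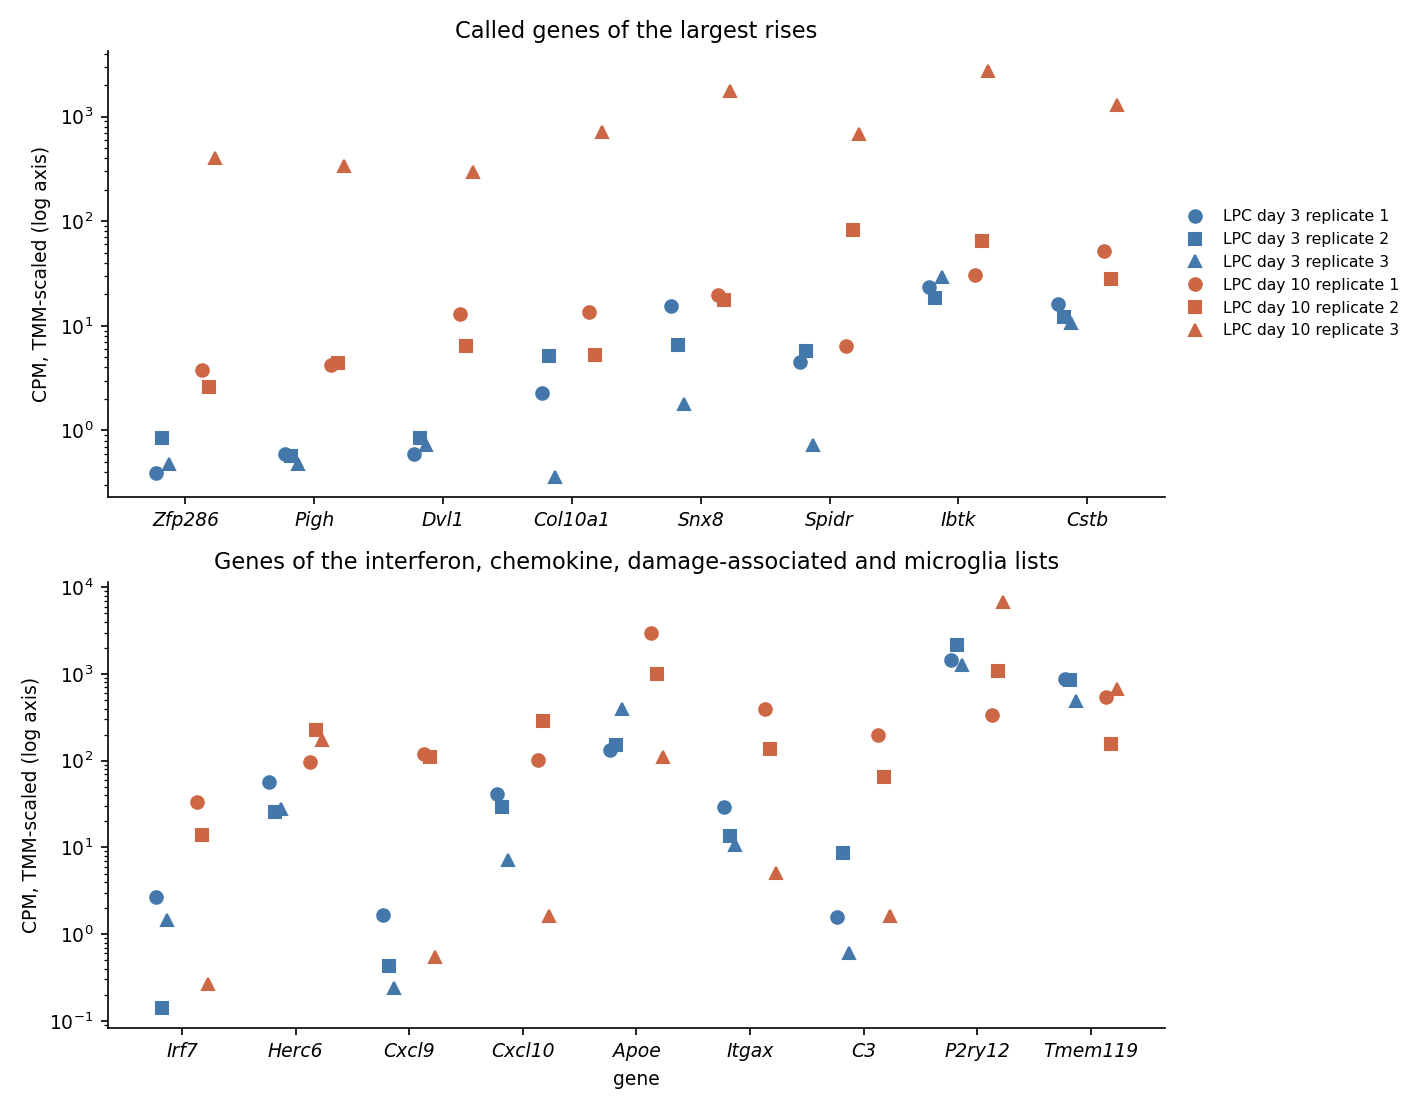
TMM-scaled CPM on a log axis of the 8 called genes of largest rise (top) and of 9 genes of the interferon, chemokine, damage-associated and microglia lists (bottom), one point per library, blue for LPC day 3 and orange for LPC day 10. The 8 called genes were highest in LPC day 10 replicate 3 (Snx8 1767 CPM), while Cxcl9, Apoe, Itgax and C3 were high in LPC day 10 replicates 1 and 2 and not in replicate 3 (Cxcl9 118, 111.5 and 0.538 CPM).

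The type I interferon-stimulated genes encode antiviral proteins and the transcription factors that drive them. The list was called higher at day 10 in camera with a preset correlation of 0.01 (adjusted p = 0.0088), and the call was lost with adjusted p = 0.984 with an estimated correlation. After the result was seen, the libraries were also grouped across time points in the preset test. LPC day 3 replicates 1 and 2 with LPC day 10 replicate 3, set against the rest, gave a camera adjusted p of 3.74e-09. Other mixed groupings gave 1.29e-06 to 0.936. No member was called over all genes tested, and 0 were called when adjusted over the list alone (edgeR, with 2 higher and 0 lower at an unadjusted p under 0.05). Herc6 and Ddx58, which encodes the RNA sensor RIG-I, had all day 10 libraries above all day 3 libraries. Herc6 had 36.9 ± 17.6 CPM at day 3 and 164.9 ± 64.4 at day 10 (SD, n = 3), with a log2 fold change of 2.16 ± 0.96 (edgeR adjusted p = 0.681), and Ddx58 had a log2 fold change of 2.05 (edgeR adjusted p = 0.673). Ddx58 had 87.7, 130.5 and 600 CPM in LPC day 10 replicates 1, 2 and 3, and a log2 fold change of 0.70 without replicate 3. Irf7 had 33.4, 13.9 and 0.269 CPM in LPC day 10 replicates 1, 2 and 3 against 1.41 ± 1.26 at day 3. Log2 fold changes were 1.77 for Isg15 and −0.06 for Ifit1 (2.32 and 0.49 without LPC day 10 replicate 3), neither of them called. The mean log2 CPM of the list was 4.78, 3.88 and 4.62 at day 3 and 5.58, 6.67 and 2.52 at day 10, so that LPC day 10 replicate 3 was the lowest of all libraries. Summed over the list, the level was 2409, 1876 and 2805 CPM at day 3 and 3077, 6976 and 3207 CPM at day 10 (two-sided exact permutation test, p = 0.1, the smallest 3 against 3 libraries can give). Most of the 3207 CPM in LPC day 10 replicate 3 came from Eif2ak2 (880.8), Trim30a (738.2) and Ddx58 (600). These had at most 282, 188 and 84.9 CPM at day 3. Eif2ak2 and Trim30a are named outside the rule. The list was not called without LPC day 3 replicate 1 (camera adjusted p 0.0518) or replicate 2 (0.288), nor without LPC day 10 replicate 1 (0.0912) or replicate 2 (0.995, with the direction turned). Without LPC day 10 replicate 3 it was called at 4.65e-12, with 38 of 41 members positive and a median of 1.45 (adjusted p = 0.318 with an estimated correlation). The list holds the close paralogs Ifit3 with Ifit3b and Oas1a with Oas1g, and how reads matching both were counted is not given in the sources used here.

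Genes of the interferon receptor and of nucleic acid sensing were not called as a list (camera adjusted p 0.921, 9 of 16 positive, median 0.14). The receptor subunits Ifnar1 and Ifnar2 had log2 fold changes of 0.79 and −0.70, and of 0.12 and −0.72 without LPC day 10 replicate 3. Irf5 had a log2 fold change of 2.61 and Tyk2, a receptor-bound kinase, of 2.10, both with their highest level in LPC day 10 replicate 3 (725.1 and 385.4 CPM, and log2 fold changes of 0.88 and 0.04 without it) and neither called.

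The damage-associated genes, a set that microglia express around plaques and injured myelin, were not called with all libraries (camera adjusted p 0.139, 21 of 28 positive, median 0.64). With all libraries they were called higher with library-size scaling (0.0436), limma-voom (0.00654) and voom with sample weights (4.01e-10). The TMM-scaled edgeR fit with an estimated correlation did not call them (0.984). The list rose without LPC day 10 replicate 3 (camera adjusted p = 1.18e-10, 24 of 30 positive, median 1.18), with adjusted p = 0.239 with an estimated correlation. In the same LPC day 10 replicates 1 and 2, summed markers of oligodendrocytes (114.2 and 72.2 CPM, against at most 34.3 at day 3) and of their progenitors (104.2 and 34.1, against at most 13.2) and the endothelial gene Flt1 (54.3 and 74.1, against at most 11.8) were also above day 3, while the endothelial genes Cdh5 and Pecam1 were not. In the fit without LPC day 10 replicate 3, 0 members were called over all genes and 8 were called higher when adjusted over the list alone, against 0 with all libraries. Apoe, the lipid carrier (ENSMUSG00000002985, chromosome 7, 19696109 to 19699188), had 134.7, 152.2 and 398.1 CPM at day 3 and 2989, 1009 and 110 CPM at day 10. Its log2 fold change was 2.59 ± 0.85 (SE, n = 3, edgeR adjusted p = 0.313) and 3.09 ± 0.58 without LPC day 10 replicate 3 (adjusted p = 0.070). Apoe was called without LPC day 10 replicate 2 (edgeR adjusted p = 0.0470) and in limma-voom with sample quality weights (1.47e-04, log2 fold change 2.76). Itgax, which encodes the integrin CD11c, had 17.7 ± 10.0 CPM at day 3 and 399.4, 136.1 and 5.11 CPM at day 10 (log2 fold change 3.35, edgeR adjusted p = 0.352). Igf1 and Spp1 had log2 fold changes of 0.70 and 0.61, and of 1.237 and 1.139 without LPC day 10 replicate 3.

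Homeostatic microglia genes mark the resting state. With all libraries the list was not called (camera adjusted p 0.892, 19 of 27 positive, median 0.20), except in voom with sample weights, which called it lower (8.37e-05). An estimated correlation was not run on that voom fit. On the edgeR fit, where the direction was higher, it gave 0.984. The list fell without LPC day 10 replicate 3 (camera adjusted p = 0.00191, 21 of 27 negative, median −0.47), with adjusted p = 0.316 with an estimated correlation. The purinergic receptor gene P2ry12 had 1638 ± 480.9 CPM at day 3 and 341.2, 1092 and 6775 CPM at day 10, a log2 fold change of 0.74 with all libraries and of −1.22 without LPC day 10 replicate 3, neither called. Tmem119 had a log2 fold change of −0.69 and Cx3cr1, the fractalkine receptor gene, of −0.42 (−1.13 and −0.94 without that library). Csf1r, which encodes the receptor that microglia need for survival, had 5733, 6005 and 5586 CPM at day 3 and 6195, 2377 and 14830 CPM at day 10 (log2 fold change 0.43, and −0.47 without LPC day 10 replicate 3). P2ry6 and Tgfbr1 had log2 fold changes of 1.90 and 1.07, and of 0.12 and −0.49 without LPC day 10 replicate 3, where both were highest. None of these genes was called.

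**Figure D3:**
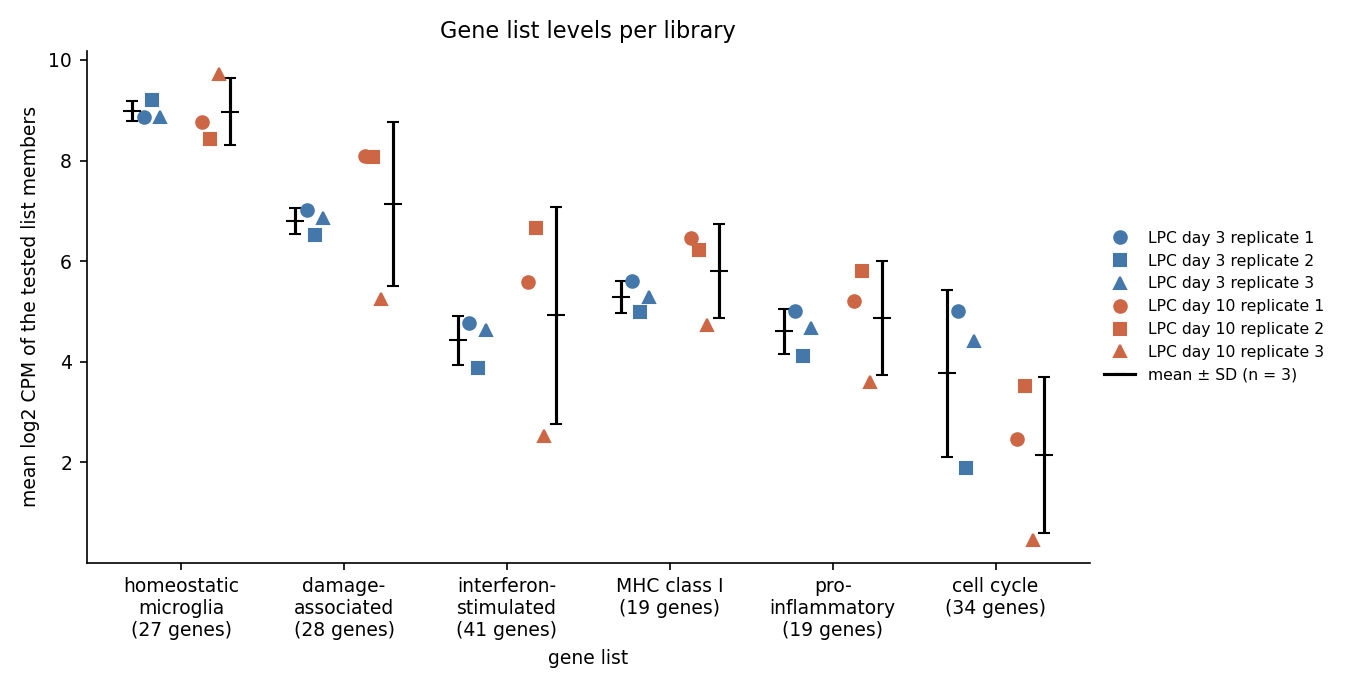
Mean log2 CPM of the tested members of 6 gene lists, one point per library, blue for LPC day 3 and orange for LPC day 10, with black bars for the group mean ± SD (n = 3). LPC day 10 replicates 1 and 2 lay above the day 3 libraries for the damage-associated (8.10 and 8.06) and interferon-stimulated lists (5.58 and 6.67), and LPC day 10 replicate 3 lay below them (5.24 and 2.52).

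MHC class I presentation genes had 17 of 19 positive changes and a median of 0.89 (camera adjusted p 0.0689, not called). With all libraries the list was called higher with upper-quartile (0.048) or library-size scaling (0.0385), limma-voom (0.044) and voom with sample weights (0.00111). The TMM-scaled edgeR fit with an estimated correlation did not call it (0.984). Without LPC day 10 replicate 3 the list rose (camera adjusted p = 0.00806, 15 of 19 positive), with adjusted p = 0.318 with an estimated correlation. The class I gene H2-T23 had 24.4 ± 12.3 CPM at day 3 and 120.7 ± 84.7 at day 10 (SD, n = 3), with no overlap between the groups (log2 fold change 2.30, edgeR adjusted p = 0.710, and 1.53 without LPC day 10 replicate 3). The proteasome activator gene Psme2 had a log2 fold change of 2.87 and its highest level, 690.4 CPM, in LPC day 10 replicate 3 (log2 fold change 0.84 without it), and was called without replicate 1 (edgeR adjusted p 0.0299). MHC class II presentation genes were not called (camera adjusted p 0.282, 4 of 6 positive). H2-Ob had 1762 CPM in LPC day 10 replicate 3 and 9.32 to 61.2 CPM elsewhere (log2 fold change −0.14 without that library), and was called without LPC day 10 replicate 1 or 2 (edgeR adjusted p 2.36e-05 and 1.98e-04) or LPC day 3 replicate 2 (0.0441), or with no filter (0.00268), while H2-Ab1 had 63.9, 19.9 and 0.807 CPM in LPC day 10 replicates 1, 2 and 3. Class I genes are close paralogs of each other, which limits how well reads separate them.

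The pro-inflammatory list was not called with all libraries (camera adjusted p 0.343, 12 of 19 positive, median 0.58) except in voom with sample weights (0.0357). An estimated correlation was run on the edgeR fit only and gave 0.984. The list was called higher without LPC day 10 replicate 3 (camera adjusted p = 0.00806, 12 of 21 positive, median 0.44), with adjusted p = 0.430 with an estimated correlation. Cxcl9, a chemokine gene induced by interferon gamma (ENSMUSG00000029417, chromosome 5, 92321347 to 92328079), had 1.67, 0.427 and 0.241 CPM at day 3 and 118, 111.5 and 0.538 CPM at day 10. Its log2 fold change was 6.57 ± 1.66 (SE, n = 3, edgeR adjusted p = 0.0985), and without LPC day 10 replicate 3 it was the 1 gene called (7.12 ± 1.10, edgeR adjusted p = 0.0194, with 0 genes lower and 416 higher and 295 lower at an unadjusted p under 0.05). With all libraries Cxcl9 was called by DESeq2 (adjusted p = 0.0063) and by edgeR with no filter (0.0101). Cxcl10, whose exons overlap those of Art3, had a log2 fold change of 2.34 and 101, 288.9 and 1.61 CPM in LPC day 10 replicates 1, 2 and 3. Tnf and Il1b, which encode inflammatory cytokines, had log2 fold changes of 1.13 and −0.60, and of 1.70 and −0.07 without LPC day 10 replicate 3. Nos2 was not tested for low counts, with 1 count in LPC day 10 replicate 2 and none elsewhere.

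The cell cycle list was lower at day 10 (camera adjusted p = 4.51e-06), and the call was lost with adjusted p = 0.984 with an estimated correlation. No member was called over all genes, and 0 were called when adjusted over the list alone (edgeR, with 0 higher and 4 lower at an unadjusted p under 0.05). Mki67, a marker of cycling cells, had 1244, 122.5 and 1180 CPM at day 3 and 122.9, 505.2 and 13.2 CPM at day 10 (log2 fold change −1.99 ± 0.91, edgeR adjusted p = 0.714), and was called without LPC day 10 replicate 2 (−3.66, 0.0201). Birc5, which encodes the mitotic protein survivin, had 7.96, 6.26 and 35.1 CPM at day 3 and 0.209, 0.215 and 0.538 CPM at day 10, with 2 counts in each day 10 library (log2 fold change −5.68 ± 2.19, edgeR adjusted p = 0.524), and DESeq2 called it (0.0202). Rrm2, a subunit of ribonucleotide reductase, had a log2 fold change of −3.97. Summed over the list, the level was 2518, 563.5 and 2639 CPM at day 3 and 442.9, 1238 and 299.3 CPM at day 10 (two-sided exact permutation test, p = 0.2, where 3 against 3 libraries cannot go below 0.1). Without LPC day 10 replicate 3 the list was called at 2.08e-04, with 33 of 36 members negative and a median of −1.02 (adjusted p = 0.692 with an estimated correlation).

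Genes of cell death pathways were not called as lists. Necroptosis genes had a median of 0.72 with 12 of 16 positive (camera adjusted p 0.788; without LPC day 10 replicate 3 a median of −0.18 with 7 of 18 positive), apoptosis genes a median of −0.08 with 8 of 17 positive (0.985) and inflammasome and pyroptosis genes a median of 0.43 with 6 of 10 positive (0.267). The kinase gene Ripk1 had 46.1 ± 25.1 CPM at day 3 and 72.5 ± 71.6 at day 10 (log2 fold change 0.65, edgeR adjusted p = 0.999, and −0.58 without LPC day 10 replicate 3). Ripk3 and Mlkl, which encode the kinase and the pore-forming effector of necroptosis, were not tested for low counts. Ripk3 had 1, 0 and 124 counts at day 3 and 0, 13 and 0 at day 10, and Mlkl had 3, 0 and 0 counts at day 3 and 0, 4 and 0 at day 10. Ripk3 was tested without LPC day 10 replicate 3, with a log2 fold change of −2.83 ± 2.70 (SE, edgeR unadjusted p = 0.306). Zbp1, a nucleic acid sensor that also belongs to the interferon list, had a log2 fold change of 0.09, and of 0.63 without LPC day 10 replicate 3. Values were 3.21 for Otulin, −3.10 for Fadd, −3.81 for Casp6, 1.92 for Casp9, 1.69 for Casp1 and 2.71 for the DNA sensor gene Aim2, and none of these was called with all libraries. Without LPC day 10 replicate 3, which had 353.1, 178 and 1923 CPM of Otulin, Casp9 and Aim2, these 3 had log2 fold changes of −0.23, 0.51 and 0.35. Fadd had 130.3 CPM in LPC day 3 replicate 1 and at most 10.9 CPM elsewhere, and Casp6 had 54.8 CPM in LPC day 3 replicate 3 and at most 7.27 CPM elsewhere. Aim2 was called without LPC day 10 replicate 1 (edgeR adjusted p 0.00491) or replicate 2 (0.0258).

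Alternative-activation genes, linked to repair, were not called (camera adjusted p 0.892, 5 of 9 positive). The mannose receptor gene Mrc1 had 19.8, 93.2 and 75.9 CPM at day 3 and 5.55, 3.88 and 6.19 CPM at day 10, with no overlap between the groups (log2 fold change −3.60 ± 1.34, edgeR adjusted p = 0.480). Mrc1 is also one of the border-associated macrophage markers, a list called lower without LPC day 10 replicate 3 (camera adjusted p = 0.0450, and 0.486 with an estimated correlation). Tgfb1 had a log2 fold change of 1.33, and of −0.17 without LPC day 10 replicate 3, and Arg1 was not tested for low counts (39, 6 and 0 counts at day 3 and 24, 1 and 0 at day 10). Secreted factors that act on the oligodendrocyte lineage were not called (camera adjusted p 0.985, 5 of 11 positive). Osm, the oncostatin M gene, had 0.342 ± 0.475 CPM at day 3 and 7.36 ± 3.46 at day 10 (log2 fold change 4.34), and Hgf, the hepatocyte growth factor gene, had a log2 fold change of −4.78 with 426 of its day 3 counts in LPC day 3 replicate 3. Matrix and matrix-remodelling genes were not called (camera adjusted p 0.985, 10 of 14 positive). The membrane metalloprotease gene Mmp14 had 36.4 ± 8.14 CPM at day 3 and 3.85 ± 5.11 at day 10, with no overlap (log2 fold change −3.22, edgeR adjusted p = 0.804). Plaur had a log2 fold change of 3.99 (edgeR adjusted p = 0.836), carried by LPC day 10 replicate 1. It had 66.5, 3.01 and 0 CPM in LPC day 10 replicates 1, 2 and 3, and 1.43 ± 1.91 CPM at day 3.

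Among lists of lipid handling and clearance, cholesterol synthesis genes were not called with all libraries (camera adjusted p 0.282, 9 of 13 positive, median 1.22). They were called higher without LPC day 10 replicate 3 (camera adjusted p = 0.0308, 12 of 17 positive, median 1.11), with adjusted p = 0.318 with an estimated correlation. Ebp had a log2 fold change of 3.02, and of 1.11 without LPC day 10 replicate 3. Camera adjusted p was 0.788 for lipid uptake, storage and efflux genes (10 of 18 positive), 0.892 for lysosomal genes (22 of 43 positive), 0.892 for phagocytic receptor and bridging genes (14 of 21 positive) and 0.565 for complement genes (6 of 11 positive). The lysosomal lipid genes Npc2 and Lipa had log2 fold changes of 2.21 and 1.85, Npc2 being called without LPC day 10 replicate 1 (edgeR adjusted p 0.0346), and Cd300lf and Dock2 of 4.47 and 2.06. All were highest in LPC day 10 replicate 3, without which the values were 0.55 for Npc2, 0.16 for Lipa, 2.27 for Cd300lf and 0.65 for Dock2. C3, the central complement protein gene, had 3.57 ± 4.33 CPM at day 3 and 195.9, 64.8 and 1.61 CPM at day 10 (log2 fold change 4.62 ± 1.46, edgeR adjusted p = 0.282).

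Camera adjusted p was 0.962 for glycolysis genes (12 of 19 positive), 0.306 for oxidative phosphorylation genes (27 of 45 negative), 0.306 for cytosolic ribosomal protein genes (40 of 68 negative) and 0.565 for immediate-early and heat-shock genes (11 of 17 positive). Log2 fold changes were 3.40 for Pfkl, −2.95 for Pfkm, 4.84 for Cox6c, 3.86 for Ndufv2, 2.58 for Rps10, −1.35 for Rpl5, 1.34 for Egr1 and 2.55 for Atf3, none of them called with all libraries by edgeR with the low-count filter. Single libraries carried several of these values: Pfkm had 55.3 CPM in LPC day 3 replicate 3 and at most 0.712 in the other day 3 libraries, and without LPC day 10 replicate 3 the log2 fold change was 1.92 for Cox6c and −0.39 for Egr1. Cox6c was called without LPC day 10 replicate 1 or 2 (edgeR adjusted p 0.00156 and 0.00384), with no filter (0.0183) and by DESeq2 (0.0244), and the ribosomal protein list fell without LPC day 3 replicate 2 (camera adjusted p 0.0457 with the preset correlation, an estimated one not being run there). Ribosomal protein genes have many processed pseudogenes, which limits how well reads separate them. Median and test differed in sign for 5 lists, none of them called. These were lysosomal genes (median 0.00, mean 0.03, test lower), alternative-activation genes (0.44, −0.09, lower), matrix genes (0.12, 0.33, lower), secreted factors (−0.11, 0.02, higher) and apoptosis genes (−0.08, 0.09, higher). Over the 23 lists, 0 of 522 memberships were called over all genes, with 28 higher and 9 lower at an unadjusted p under 0.05. Adjusted over the list alone, 6 were higher, among them H2-Ob, Cox6c, Cxcl9, Itgax and C3, and 0 lower. H2-Ob and Cox6c had their highest level in LPC day 10 replicate 3, and Cxcl9, Itgax and C3 in replicates 1 and 2. Without LPC day 10 replicate 3 the median changed sign for 9 of the 23 lists and the direction of the test for 8. Of 78 named genes in both fits, 12 changed sign and 20 more kept under 0.5 of their log2 fold change. Without that library, 16 of 548 memberships were higher and 1 lower when adjusted over the list alone.

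**Figure D4:**
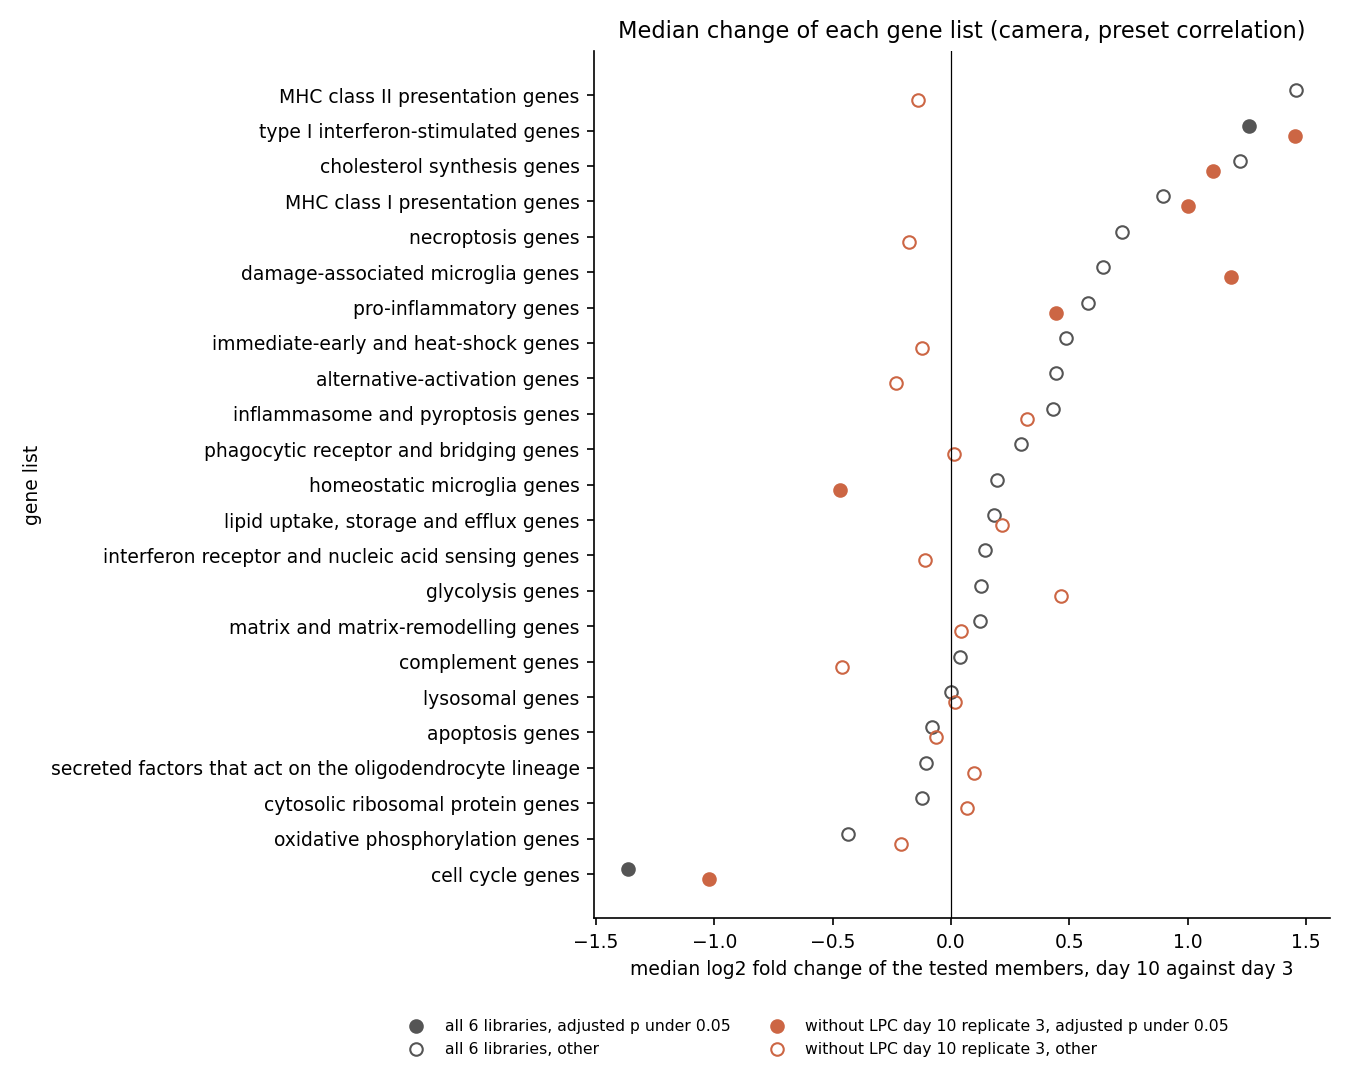
Median log2 fold change of the tested members of each of the 23 gene lists, day 10 against day 3, with all 6 libraries (grey) and without LPC day 10 replicate 3 (orange), filled where camera with the preset correlation gave an adjusted p under 0.05. With all libraries 1 list was higher and 1 lower, and without LPC day 10 replicate 3 there were 5 higher and 2 lower, where an estimated correlation gave 0 in either fit.

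Markers of other cell types were measured because the gate (CD11b positive, Ly6G and CD3 negative, CD45 low) could hold other cells. Only 3 of the 14 marker lists had at least 3 tested members. Endothelial markers were higher at day 10 (camera adjusted p = 0.0382, 2 of 3 members positive, median 2.35), with adjusted p = 0.250 with an estimated correlation. The call was lost without LPC day 3 replicate 2 or 3 and without LPC day 10 replicate 1 or 2, each with 0 marker lists called. Flt1 had 54.3, 74.1 and 1.35 CPM in LPC day 10 replicates 1, 2 and 3, while Cldn5 and Tek had no counts. Cdh5 had 6.29, 0.142 and 10.7 CPM at day 3 and 0, 0.215 and 0.269 at day 10, Pecam1 7.37, 1.71 and 0 at day 3 and 1.68, 6.14 and 0.538 at day 10, and Kdr at most 0.844 at day 3 and 11.4, 14.2 and 14.8 at day 10. Border-associated macrophage markers (camera adjusted p 0.142) and monocyte-derived macrophage markers (0.995) were not called. For border-associated macrophage markers the median was 0.30 while the mean was −0.94 and the test direction was lower, and for monocyte-derived macrophage markers the median was 0.10 with a mean of −0.04. Border-associated macrophage markers fell without LPC day 10 replicate 3 (camera adjusted p = 0.0450), with adjusted p = 0.486 with an estimated correlation, and endothelial markers were not called (0.155). Stab1 had 335.7 ± 74.3 CPM at day 3 and 183.3, 49.5 and 1007 CPM at day 10, and a log2 fold change of −1.57 without LPC day 10 replicate 3.

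Neutrophil markers summed to 113.3 CPM in LPC day 3 replicate 3, where S100a8 had 55.0 CPM, and to at most 0.295 CPM in each other library. Oligodendrocyte markers summed to 34.3, 26.6 and 27.0 CPM at day 3 and 114.2, 72.2 and 15.6 CPM at day 10, mostly from Mbp and Cnp. Oligodendrocyte progenitor markers summed to 104.2 and 34.1 CPM in LPC day 10 replicates 1 and 2, nearly all from Cspg4, against at most 13.2 CPM elsewhere. B cell markers summed to 653.5 ± 143.9 CPM at day 3 and 495.5 ± 175.3 at day 10 (SD, n = 3), mostly from Ighm, while Pax5 had no counts. Group sums of monocyte-derived macrophage markers, the most abundant Fn1, were 131 ± 121 and 105.1 ± 92.3 CPM at days 3 and 10. They were 445.1 ± 75 and 475.5 ± 480.6 CPM for border-associated macrophage markers, and 89.0 ± 50.2 and 57.0 ± 13.9 CPM for astrocyte markers, mostly Slc1a3. T cell markers, mostly Il7r, summed to 98.7 CPM and dendritic cell markers, mostly Itgae, to 226.4 CPM in LPC day 10 replicate 3, against at most 54.4 and 34.4 CPM elsewhere. Itgae was called higher without LPC day 10 replicate 1 or 2 (edgeR adjusted p 0.0371 and 0.0465), and had a log2 fold change of −0.59 without replicate 3. Mean sums per group were under 10 CPM for natural killer cell (Klrd1), neuron (Rbfox3), pericyte and fibroblast (Acta2) and erythroid (Alas2) markers. In a two-sided exact permutation test of each marker sum the lowest p was 0.2, where the smallest this design allows is 0.1.

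The authors' deposited table of log2 fold changes gives day 3 minus day 10, opposite in sign to the values here. With the sign turned, its values and those fitted here correlated at Pearson r = 0.862 across 10535 genes, which are not independent replicates, and 85.1% had the same sign. All 12 called genes had the same sign there, and 6 of them had a deposited unadjusted p under 0.05. There, 1020 genes had a p under 0.05, 636 of them higher at day 10 and 384 higher at day 3. The lowest deposited p was 6.84e-05, and the lowest after a Benjamini-Hochberg adjustment made here was 0.834.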

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

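The robust edgeR fit and the 3 scalings without LPC day 10 replicate 3 were chosen after the result was seen. The count of 12 genes higher at day 10 became 0 with RLE factors, library size only, limma-voom, the replicate block, each of the 3 limma-trend fits on FPKM, or an adjusted p under 0.01. It was 2 with voom and sample quality weights, 20 with the 1 CPM filter, 80 with DESeq2 and 113 with no filter, and ran from 1 to 208 when 1 library was left out. Upper-quartile scaling gave 10, of which 9 were shared, and the robust fit 15, of which 7 were shared. DESeq2 gave no p for 11 of the 12 genes, and 49 of its 113 calls were highest in LPC day 10 replicate 3. Genes lower at day 10 numbered 5 with no filter, 33 with DESeq2, 0 to 4 with 1 library left out, and 1 each with the 1 CPM filter, limma-voom, voom with weights and the robust fit. RLE factors moved the median log2 fold change of all tested genes by 0.13. The cause of these differences in calls was not tested.

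Lists higher at day 10, 1 in the report, numbered 0 with no filter, with the replicate block, with an estimated correlation and with fry, 2 with upper-quartile scaling, 3 with library size only, 3 with limma-voom, 4 with voom and weights, and 0 to 5 with 1 library left out. Without LPC day 10 replicate 3 they numbered 5 with RLE or upper-quartile and 6 with library-size scaling, and lists lower numbered 2 with each. Lists lower, 1 in the report, numbered 2 with voom and weights, 0 with an estimated correlation or fry, and 1 to 2 with 1 library left out. Marker lists called, 1 in the report, numbered 2 with limma-voom, 2 with voom and weights, 0 with an estimated correlation or fry, and 0 to 1 with 1 library left out. The adjusted p of the interferon list was 0.069 with no filter, 0.174 with the replicate block, 0.984 with an estimated correlation, 0.976 with fry and 4.65e-12 to 0.995 with 1 library left out, the last without LPC day 10 replicate 2 and with the direction reversed. That of the cell cycle list was 0.984 with an estimated correlation, 0.976 with fry and 1.33e-12 to 0.0194 with 1 library left out. The homeostatic list was reversed, to lower, with voom and weights (8.37e-05) and without LPC day 10 replicate 3 (0.00191), and its adjusted p ran from 0.00191 to 0.981 with 1 library left out. To look for a pairing, libraries of the 2 time points were correlated after each gene's group mean was taken off. Pairs of the same replicate number had 0.0733, −0.0351 and 0.00727, against −0.0805 to 0.0631 for the other pairs. So 1 lay above that range, and these values leave open whether the block removes a pairing. The levels themselves, as log2 CPM, correlated at Pearson r = 0.650, 0.670 and 0.575 in the same-number pairs. For single results, direction and side of the threshold were kept in 1276 values of named genes and 298 of lists, the threshold was lost in 86 and 9 and newly passed in 25 and 13, and the sign turned below the threshold in 92 and 45.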

Other observations

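The tests of the share of genes under 2 CPM, of the ratio of homeostatic to damage-associated genes, of the homeostatic list, of lists outside the pattern, of monocyte and oligodendrocyte markers, of the cell cycle list without LPC day 10 replicate 3 and of other splits of the libraries were chosen after the result was seen, as were the genes in the next paragraph.

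In LPC day 10 replicates 1 and 2, further genes lay apart from day 3, none of them called in the edgeR fit without replicate 3, which gave the log2 fold changes below. Slc26a11, an anion transporter gene, had 73.8, 70.2 and 104.1 CPM at day 3 and 1.00 and 0.351 CPM at day 10, a log2 fold change of −6.90 (adjusted p = 0.070). Tspan18 had a log2 fold change of −4.09 (0.101), and Plxna4 and Tifab of −2.34 and −2.29. Among the damage-associated genes, Lpl, the lipoprotein lipase gene, had 2.27, Cst7 2.83 and Gpnmb 4.98. Tnfsf10, which encodes the death ligand TRAIL, had 4.91 (0.634), with 58.4 and 69.9 CPM at day 10 against at most 5.52 CPM at day 3. The interferon-inducible gene Ifi211 had 5.81 (0.604). Art3 (9.51) shares exons with Cxcl10, so its counts do not stand alone.

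Genes far higher in LPC day 10 replicate 3 than in each other library numbered 357 and included all 12 called genes. Their median log2 fold change in replicates 1 and 2 was 0.17 (quartiles −0.50 and 0.92), which decides nothing about a rise shared by the day 10 libraries, since the genes were chosen for lying above those replicates. That few RNA molecules of this library entered amplification stays open as a candidate explanation: over 113 ribosomal protein and oxidative phosphorylation genes the SD of the log2 difference from the other libraries was 2.25, against at most 1.42, and 8.46% of 2779 genes abundant elsewhere were under 2 CPM, against at most 0.272%. A first test, with its rule set before its result was seen, took the share of such genes at 0 counts. By that rule a share no higher than in the other libraries counted against few molecules, and it was 0.0% in each library. A share of 0 in every library separates none, so this outcome was not used to decide. Of the 10 splits of the 6 libraries, 1, the real one, called 12 genes and the highest other called 0, too few splits for a share under 0.05.

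In mean log2 CPM, interferon-stimulated and damage-associated genes were higher in LPC day 10 replicates 1 and 2 than at day 3 and lower in replicate 3. Summed, the interferon-stimulated genes in replicate 3 (3207 CPM) lay above each day 3 library (1876 to 2805 CPM). Most of that sum came from Eif2ak2 (880.8), Trim30a (738.2) and Ddx58 (600). Low detection in replicate 3 cannot be told apart from a deficit of these genes. Their mean log2 difference there was −2.26, below random lists matched on expression (95% between −0.94 and 0.17), but 5 of 21 lists outside the pattern also lay below their own random lists. Among these were ribosomal protein (−2.15), glycolysis (−2.13) and oxidative phosphorylation genes (−1.94), so the random lists are too narrow to decide. Gene length stays open for the same reason: lists matched also on exon length reached −1.21 at their 2.5th percentile, and 3 of the 21 lay below theirs. That replicate 3 held fewer activated lesion microglia stays open as well. Its ratio of homeostatic to damage-associated CPM was 13.8, against 1.28 to 4.05 elsewhere, which restates the low damage-associated level. The homeostatic genes, not part of the pattern, had a mean log2 difference of 0.89, inside random lists matched on expression (−0.41 to 0.94) and above those matched also on exon length (−1.04 to 0.49), and random lists this narrow leave it undecided. Monocyte-derived cells in replicates 1 and 2, which the CD45 low gate is meant to remove, cannot be told apart from microglia. Their marker sums (204.7 and 88.1 CPM, of which Fn1 alone had 195.2 and 67.5) lay within the day 3 range of 17.5 to 258.4 CPM. RNA of oligodendrocytes in replicates 1 and 2 cannot be excluded either: their markers summed to at least 72.2 CPM there, against at most 34.3 CPM at day 3. The mean gain of these markers over day 3 was 63.9 CPM, against 2663 CPM for the interferon-stimulated and 7201 CPM for the damage-associated genes. Of the 10 splits, 6, the real one included, called at least 2 lists. The real one called 2 and the highest other 6, so the number of lists called does not set the time points apart from mixed groupings.

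The cell cycle list was called lower at day 10 with the preset correlation. Low detection in LPC day 10 replicate 3 as the whole cause stays undecided. Without that library the list was still called with the preset correlation (camera adjusted p = 0.000208). That test cannot decide, since it also gave 3.88e-14 for a grouping that mixed the time points. With an estimated correlation the call was lost both without LPC day 10 replicate 3 (0.692) and with all libraries (0.984). The members lay at −2.67 in that library against −1.96 to −0.13 for random matched lists. A difference between the time points stays open: LPC day 3 replicate 2 had a low sum of 563.5 CPM and LPC day 10 replicate 2 a high one of 1238 CPM, so that the groups overlapped (exact permutation p = 0.2). Of the 10 splits, 2 gave an adjusted p of this list as small, the real one (4.51e-06) included. The lowest other was 3.88e-14, for LPC day 3 replicates 1 and 3 with LPC day 10 replicate 2. The real grouping was thus not the most extreme, and the splits are too few for a share under 0.05.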
